A study of Mus musculus with 8 samples.

How the data were processed

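Gene expression was measured in mouse neurospheres, free-floating clusters grown from neural stem cells, on 8 single-colour (Cy3) Agilent arrays of 1 slide. Per the labels, the cells came from the ganglionic eminence of embryos at day 14.5, each sample was grown from a single embryonic brain, and quaternary neurospheres were used. The labels give 3 groups: wild-type floating (3 arrays), Cbx3-deficient floating (3 arrays) and Cbx3-deficient adherent (2 arrays), called WT and KO here. The culture protocol in the labels describes low-attachment plates for every sample, and the adherent culture is not described further in the sources used here.

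The deposited scanner files hold the spot intensity on a linear scale. Per the file headers they were made by Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes name version 9.1.3.1. The authors' value table was compared with the scanner files: 99.2% of the 55681 probe intensity values of the array labelled WT floating 1 lay within 0.01% of its processed signal, so the deposited table is linear, uncentred and not normalized between arrays.

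From the processed signal, log2 values were taken and each array's 75th percentile over non-control spots was subtracted. Spots flagged as outliers were left out, which left 200 probes without a value on at least 1 array, and repeated spots were averaged. To be tested, a probe had to be well above background on every array of at least 1 group, and the probe with the highest mean stood for each gene. The files pair probes with accessions but not with gene names. Without versions, 27235 of 55681 probes matched a gene in a RefSeq table of the GRCm38.p6 assembly. Probes without a match stayed as their own feature. In all, 22647 features were tested, 13204 of them with a gene symbol. The 75th percentile of processed signal ranged from 616 to 865 and the share of non-control spots above background from 44.5% to 55.4%.

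Features were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes, two-sided) in a fit of all 8 arrays with 3 groups. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Gene lists, 29 in all and 1 of them of sex-linked genes used only as a check, were tested with camera at a preset correlation of 0.01 where 3 or more members were measured, with adjustment over lists and both contrasts. Camera with an estimated correlation and fry, which tests each list by itself, were run beside it. Where a gene was not well above background on any array of the dimmer group, the fold is a bound: the brighter group's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

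Groups, tests, gene lists, the rule for named genes and the other settings tried were fixed before the data were examined. The rule named Cbx3, then up to 12 genes per direction with the largest change among genes past the threshold whose arrays did not overlap between groups and that were above background on every array of the higher group, without clone or predicted names, and up to 4 passing members of each list. Where a list had no passing member, up to 2 of its brightest members could be given with values.

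Some choices were made after the data were seen. The Cbx3 signal opposed the labels of 2 arrays, so each count was repeated without them. A further fit without them, which joined the 4 remaining KO-labelled arrays of both cultures into 1 group, was added after the first repeat had been computed. The rule for named genes was then applied to both. The settings fixed beforehand were quantile normalization, the median of detected probes, normexp background correction with an offset of 50, the authors' value table, other probe filters, every probe, only the groups compared, an intensity trend with robust eBayes, array weights, replicate and slide-row blocks, a 2-fold minimum and leaving out each array. The files hold no mean spot signal, so normexp was run on the median signal. The default array weights did not converge, and weights estimated gene by gene were added.

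Same-numbered floating arrays deviated together from their group means (r across genes of 0.103, 0.590 and 0.335 for numbers 1, 2 and 3). Some differently numbered arrays did so as much (0.346 for WT floating 1 with KO floating 3, 0.205 for WT floating 3 with KO floating 1). Same-numbered pairs with an adherent array were negative (-0.630 to -0.0544), but deviations in a group of 2 mirror each other, so these signs cannot decide. The WT floating and adherent deviations are taken from means that hold an array whose Cbx3 signal opposed its label. The pairing is uncertain. By the rule set beforehand, correlations over 0.1 count as pairing, and the value with the replicate block is given where it changes a call. The fits were tested on simulated data with 200 changed genes. For KO against WT floating on 22647 features, 17.9% of 2-fold, 74.6% of 4-fold and 78.8% of 8-fold changes were recovered. In the same fit 11 unchanged features passed. The simulated changes followed all labels, and the noise was independent between arrays. These shares thus do not hold for genes that, like Cbx3, oppose the labels of 2 arrays. Without the 2 arrays, on 25962 features, the shares were 0%, 31.3% and 54.5%.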

Results

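The expression of neurospheres was compared between wild-type and Cbx3-deficient mice, and between floating and adherent culture of the Cbx3-deficient cells. Cbx3 encodes HP1gamma, a chromatin protein that binds methylated histone H3. The series title names a loss of H3K27 methylation at neuronal genes under this deficiency as its subject. There were 3 WT floating, 3 KO floating and 2 KO adherent arrays, each grown from a single embryonic brain per the labels. Whether a floating and an adherent array share an embryo is not given in the sources used here.

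The Cbx3 signal fell into 2 separate levels that did not follow all labels. On the log2 scale relative to each array's 75th percentile, it was 5.83 and 5.95 on the arrays labelled WT floating 1 and 3, but -2.17 on the array labelled WT floating 2. The arrays labelled KO floating 1, 2 and 3 had -1.86, -2.76 and -1.75, and the array labelled KO adherent 1 had -2.03. The array labelled KO adherent 2 had 5.91. The gap between the 2 levels was 7.59 on the log2 scale, 192-fold, and a second Cbx3 probe split the arrays the same way with a gap of 5.48. Whether the probes lie in the deleted part of the gene is not given in the sources used here. The labels were kept in all comparisons below, and directions that involve these 2 arrays carry this doubt.

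**Figure D1:**
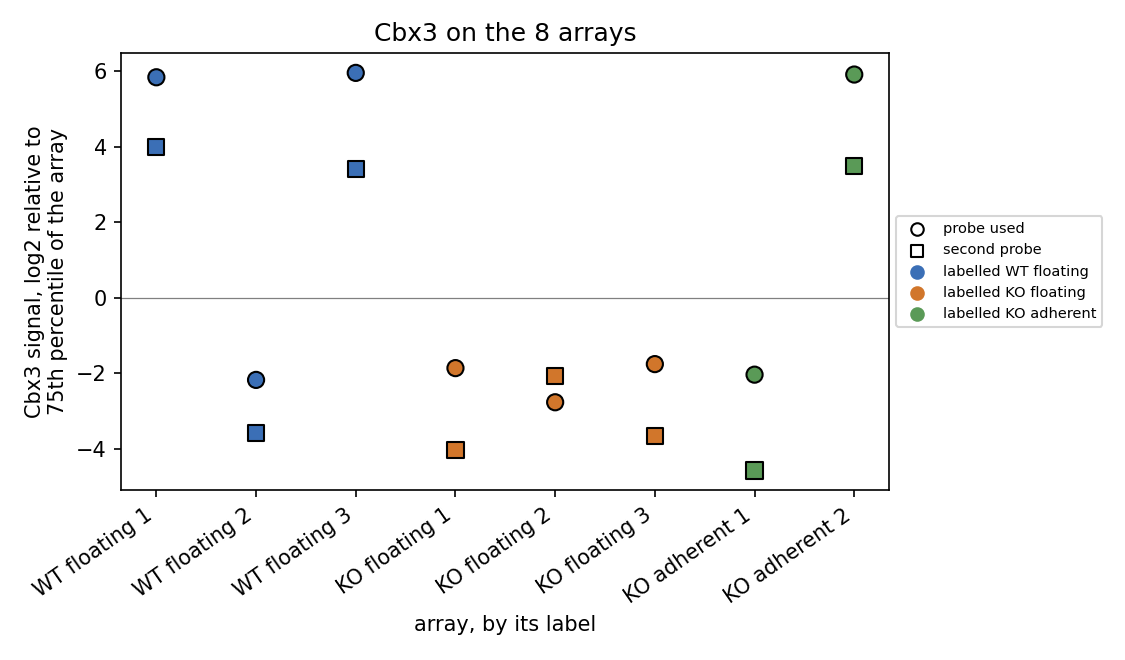
Cbx3 signal (y axis, log2 relative to the array's 75th percentile) on each of the 8 arrays (x axis, by label); circles show the probe used, squares the second probe, and colours the labelled group. The array labelled WT floating 2 lies at -2.17, with the KO floating arrays, and the array labelled KO adherent 2 at 5.91, with the other WT floating arrays.

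The arrays also grouped by overall expression in a way that crossed the labels. The array labelled WT floating 2 correlated best with KO floating 2 (r = 0.992 across probes, which are not independent replicates), and the array labelled KO adherent 2 with WT floating 3 (r = 0.989). WT floating 2 and KO floating 2 also share a number and lie side by side on the slide. The immediate early gene Nr4a1 had 4.50 and 4.83 on them and 7.43 or more on all other arrays. Their correlation thus cannot be tied to the Cbx3 level alone. KO floating 1 and KO adherent 1, which share a number, had the highest correlation of all pairs (r = 0.9919). KO floating 3 stood apart on the second component. Among the sex-linked genes, Ddx3y and Eif2s3y of the Y chromosome were above background on WT floating 1 and KO floating 3 alone. Xist was above background on all arrays but these. Sex thus differed within both floating groups and was not part of any fit. The arrays labelled WT floating 2 and KO adherent 2 had the same pattern, so sex does not tell them apart.

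**Figure D2:**
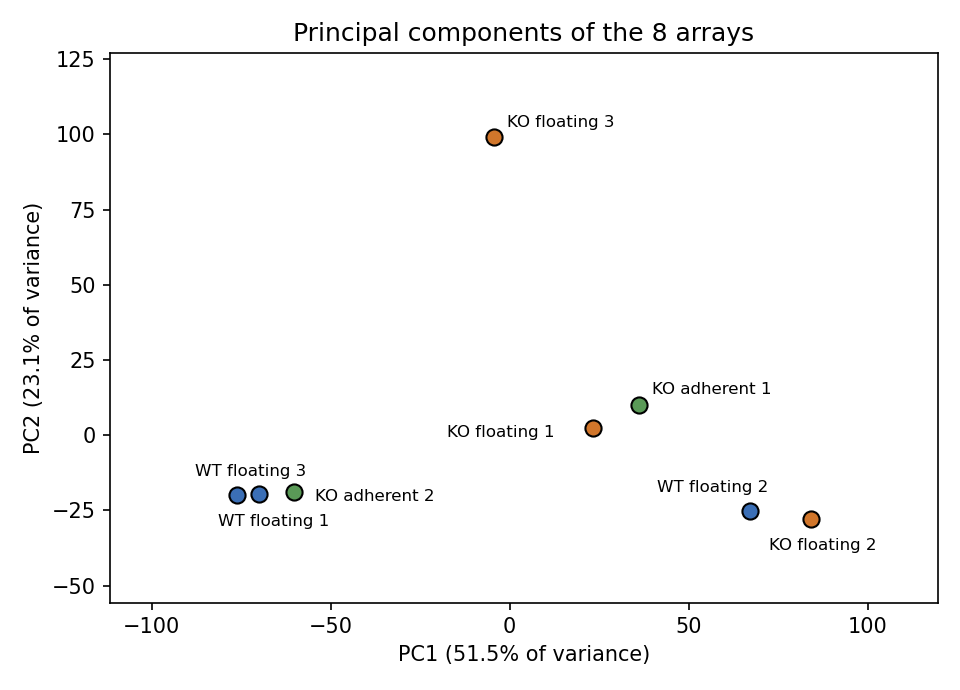
First and second principal components of the 8 arrays (axes in component units, with the percent of variance); colours show the labelled group, blue for WT floating, orange for KO floating and green for KO adherent. The array labelled KO adherent 2 lies beside WT floating 1 and 3, and the array labelled WT floating 2 beside KO floating 2.

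In KO against WT floating neurospheres as labelled, the single gene past the threshold was Gm14207, a predicted gene. It was above background on all 3 WT floating arrays and on 0 of 3 KO floating arrays, at least 3.03-fold lower in KO (limma adjusted p = 0.0136), and was named after its values were seen. Cbx3 averaged -2.13 ± 0.55 (SD, n = 3) in KO and 3.20 ± 4.66 (SD, n = 3) in WT, a difference of -5.33 (SE 2.63) that did not pass (limma adjusted p = 0.813). Without the array labelled WT floating 2 alone the Cbx3 difference was -8.02 and did not pass either (limma adjusted p = 0.232). The 2 adherent arrays, at -2.03 and 5.91, still entered the spread that the groups share in that fit. Ccnd1, a G1 cyclin, averaged 4.30 ± 0.41 in KO and 5.86 ± 0.91 in WT (SD, n = 3 each), not past the threshold (limma adjusted p = 0.813). Of 22647 features, 391 had an unadjusted p under 0.05 in limma, against 1132 from chance alone. With a replicate block, 0 features passed.

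Among the gene lists, 7 of 28 passed camera in this comparison. Cell cycle genes were lower in KO in 33 of 33 measured members (median log2 difference -0.42, adjusted p = 6.62e-07; 0.0733 without the 2 arrays), and clustered protocadherins, adhesion proteins of neurons, were higher in 21 of 24 (median 0.64, adjusted p = 0.000304). The Hox list is among the 7, but 5 of its 39 genes passed the probe filter and none of them through the WT group, which fixes their direction, so its result is no test. Astrocyte genes (median 0.34), proneural transcription factors (0.43) and neural stem genes (0.36; adjusted p = 0.0481, and 0.0867 without the 2 arrays) also shifted up, and extracellular matrix genes (-0.24) down. No member of these lists passed by itself, adjusted over all genes or adjusted over the list alone. With an estimated correlation 0 lists passed: the p was 0.642 for 6 of the 7 lists and 0.753 for extracellular matrix.

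A fit without the arrays labelled WT floating 2 and KO adherent 2 was added after the Cbx3 values were seen. In it, KO floating (n = 3) and WT floating (n = 2) differed in 46 of 25962 features, 25 higher and 21 lower in KO. An unadjusted p under 0.05 in limma was found for 6563 features, against 1298 from chance alone. The highest other split of these floating arrays gave 4314. Since the 2 arrays were left out for their Cbx3 level, the call of Cbx3 itself (log2 difference -8.02, SE 0.35, limma adjusted p = 0.014) is no independent result. Aldh1a1, which makes retinoic acid, rose from -0.69 ± 0.40 (SD, n = 2) to 3.02 ± 0.40 (SD, n = 3; limma adjusted p = 0.0489), while Aldh1a3, an enzyme of the same reaction, fell and was at least 19-fold lower (adjusted p = 0.0349). Cyp2b13, a cytochrome P450, rose at least 25.6-fold, Zfp982, a zinc finger gene, at least 7.66-fold, Hoxa7 at least 8.65-fold and the protocadherin Pcdha9 at least 3.90-fold. Smim20, a mitochondrial protein, fell at least 37.6-fold, Plaur, the urokinase receptor, at least 7.43-fold, and Vdr, the vitamin D receptor, at least 5.22-fold. On the features of the fit of all 8 arrays the count was 131 (100 higher, 31 lower). With a replicate block it was 0, and it was also 0 without WT floating 3, KO floating 1 or KO floating 3, 5 without KO floating 2, 320 without WT floating 1 and 462 without KO adherent 1.

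**Figure D3:**
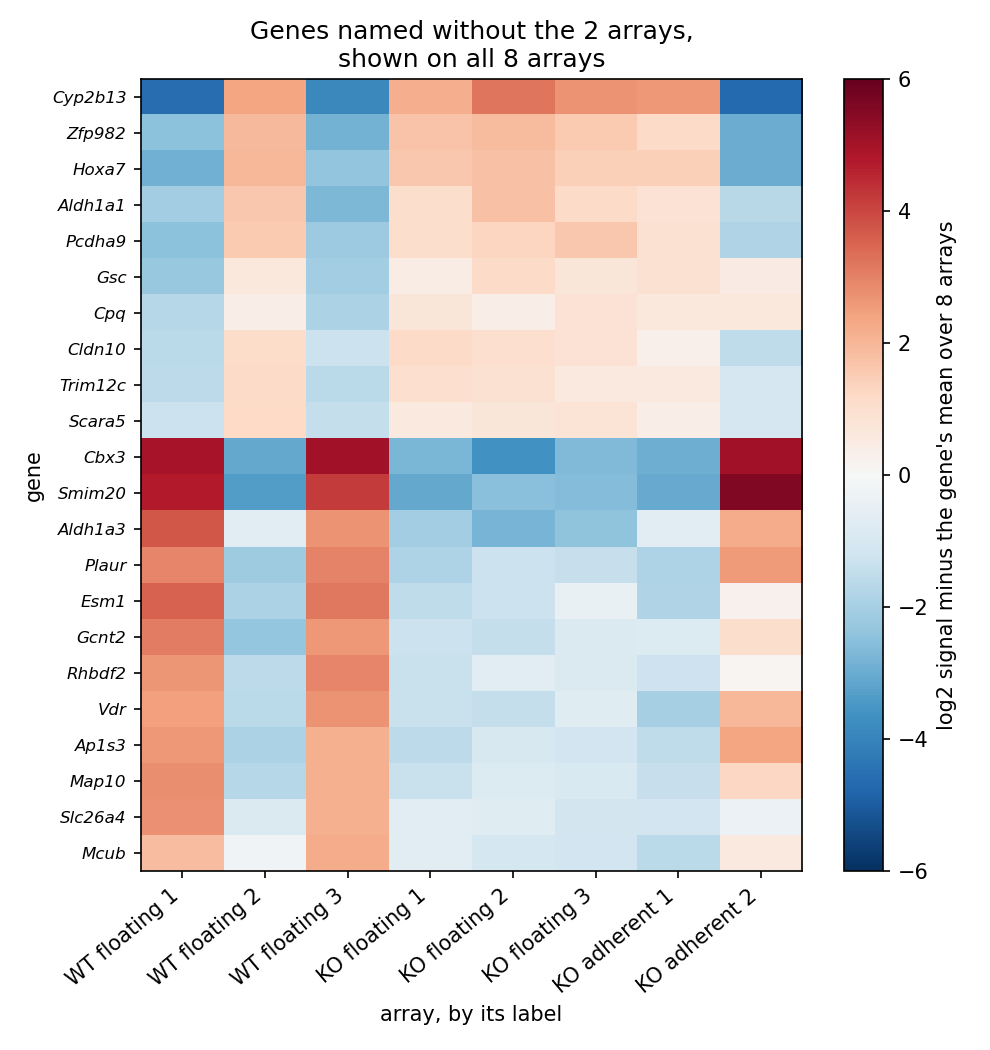
Genes named without the 2 arrays (rows), on all 8 arrays (columns, by label); colour shows log2 signal minus the gene's mean over 8 arrays. The genes were chosen for differing among 5 of the floating arrays; the 2 arrays left out of the choice are shown too, and Cbx3 lies at -2.17 on WT floating 2 and 5.91 on KO adherent 2.

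When the 4 remaining KO-labelled arrays of both cultures were joined and compared with WT floating 1 and 3, a fit added later still, 3722 of 21463 features passed, 1929 higher and 1793 lower in KO. With the features of the preceding fit, tried first, the count was 1981. In the joined fit 8102 features had an unadjusted p under 0.05 in limma, against 1073 from chance alone. The highest other split of these arrays gave 3751. All 46 features of the preceding fit passed here in the same direction, which is nearly built in, as both fits hold the same 6 arrays. Clustered protocadherins rose (22 of 23 members higher, median 1.40, camera adjusted p = 2.98e-07; 10 passed adjusted over all genes and 11 adjusted over the list alone), among them Pcdhac2 by 3.00 (SE 0.27) and Pcdha8 by 2.78 (SE 0.30). Some members, such as Pcdha9, passed the filter through KO arrays alone, but with probes above background on all arrays the list kept its call (median 1.08, camera adjusted p = 5.22e-06). With an estimated correlation 0 lists passed (adjusted p = 0.372 for the protocadherins). Of 39 Hox genes 4 passed the probe filter, all of the Hoxa cluster and none through the WT group, so their shared direction is fixed by the filter. Without the filter the Hox list had a median of -0.49 (camera adjusted p = 0.732). Hoxa3 was at least 17.1-fold higher (limma adjusted p = 0.0112) and Hoxa7 at least 8.44-fold (adjusted p = 0.000828).

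Genes of the neural lineage moved in both directions in this fit. Of 20 neural stem genes 5 rose and 2 fell: Hes5, a Notch effector, rose by 3.22 (SE 0.32, limma adjusted p = 0.00762) and Nr2e1 by 1.04 (SE 0.20), while Vim fell by 0.68 (SE 0.16). Of 19 astrocyte genes 8 rose and 2 fell, with Aldoc up by 2.79 (SE 0.48), S100b up by 1.51 (SE 0.23) and Gfap at -2.35 (SE 0.40), above background on 1 of 4 KO arrays and with 1 of its 2 other probes of opposite sign. Proneural factors rose in 4 of 10 members, including Myt1 by at least 2.21-fold, which passed the probe filter through KO arrays alone. Of 21 pan-neuronal genes 6 rose and 1 fell, with Tubb3, neuronal tubulin, up by 1.26 (SE 0.16), although this list did not pass camera (adjusted p = 0.118). With an estimated correlation the adjusted p was 0.372 for the stem, astrocyte and proneural lists.

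Oligodendrocyte genes, imprinted genes and interferon-stimulated genes had passing members in both directions, and none of these lists passed camera. Of 14 oligodendrocyte genes 5 rose and 2 fell: Olig1 rose by 1.93 (SE 0.22), while Mbp, a myelin protein, was at -1.56 (SE 0.35), with 1 of its 2 other probes of the same sign. Of 23 imprinted genes 3 rose and 4 fell, with Nnat up by 1.59 (SE 0.39) and Peg10 at -2.32 (SE 0.41). Of 22 interferon-stimulated genes 2 rose and 3 fell, with Rtp4 up by 1.02 (SE 0.14) and Gbp2 at -2.15 (SE 0.30). Among inhibitors of the cell cycle, Cdkn2a rose by 1.17 (SE 0.28) and Cdkn2b fell by 1.08 (SE 0.28). The largest rises beside Cyp2b13 and Hox genes included Dscaml1, an adhesion molecule, at least 13.4-fold, and Tal1, a blood transcription factor, at least 6.31-fold.

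Matrix genes were lower in the joined fit, and cell cycle genes were lower with both WT arrays in it. Of 33 cell cycle genes 3 fell and 0 rose (median -0.38, camera adjusted p = 0.0286), among them Ccnd1, from 6.39 ± 0.01 (SD, n = 2) to 4.08 ± 0.56 (SD, n = 4), and Ccnd2. Without WT floating 3 the cell cycle median was -0.017 and the direction of its test turned (camera adjusted p = 0.9). Of 35 extracellular matrix genes 10 fell and 2 rose, with Timp1, a metalloproteinase inhibitor, at -4.30 (SE 0.66), Tnc at -2.09 (SE 0.38) and, in the other direction, Cdh11 at 2.95 (SE 0.45). Cholesterol synthesis genes were lower in 19 of 21 members (camera adjusted p = 0.0274). With an estimated correlation the adjusted p was 0.819 for cell cycle and 0.753 for matrix and cholesterol genes. The count was 635 without WT floating 3, 697 without KO floating 1 and 903 without WT floating 1. Without KO adherent 1 the joined fit is the same as the fit with the cultures apart without that array, whose lower count is given there. The joined fit cannot separate culture from genotype for the array labelled KO adherent 1. If KO floating 1 and KO adherent 1 share an embryo, its 4 KO arrays are not independent.

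In KO adherent against KO floating neurospheres as labelled, 0 of 22647 features passed limma, with 253 at an unadjusted p under 0.05 and a smallest adjusted p of 0.215. Immediate early and stress genes were higher in adherent culture in 25 of 25 measured members (median 0.78, camera adjusted p = 0.00724), and hypoxia and glycolysis genes in 23 of 23 (median 0.43, adjusted p = 0.00462). The stress genes' direction rests on KO floating 2: the median was -0.057 without that array, and -0.061 with the slide row as a block. Nr4a1, an immediate early transcription factor, averaged 7.97 ± 0.06 (SD, n = 2) in adherent and 6.91 ± 1.81 (SD, n = 3) in floating culture, where KO floating 2 had 4.83 and the other 2 arrays 7.96 each, and Gapdh, a glycolytic enzyme, differed by 0.19 (SE 0.31), neither past the threshold (limma adjusted p = 0.99 each). Clustered protocadherins were lower in 21 of 24 members (median -0.36, adjusted p = 3.63e-05), as were astrocyte (median -0.27) and pan-neuronal genes (-0.25). None of these 3 shifts was seen without the 2 arrays, where protocadherins were higher in 15 of 28 members (median 0.02, with the test's direction down, adjusted p = 0.152) and the adjusted p was 0.25 for astrocyte and 0.548 for pan-neuronal genes. With an estimated correlation 0 lists passed (adjusted p = 0.799 for stress and 0.786 for hypoxia genes), and without KO floating 2 the preset test passed 0 lists. Without the 2 arrays, which leaves 1 adherent array assumed to vary like the other groups, 0 features passed limma and 1000 had an unadjusted p under 0.05. The lists that passed there were others: cell cycle (median -0.34), cholesterol synthesis (-0.47) and microglia genes (0.34), each with an adjusted p of 0.726 with an estimated correlation.

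KO adherent against WT floating, where genotype and culture differ together, again gave 1 feature of 22647, Gm14207, which was above background on 0 of 2 adherent and 3 of 3 WT floating arrays (limma adjusted p = 0.0227). With a replicate block it was 0, and without the 2 arrays 4 of 25962 features passed. Since 0 features passed in KO adherent against KO floating, features shared with KO against WT floating could not be assessed.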

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

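The fits without the 2 arrays and the weights gene by gene were chosen after the result was seen. The count for KO against WT floating as labelled, 1 feature, fell to 0 with normexp, with no filter, with probes above background on all arrays, with only the 2 groups compared, with the intensity trend and robust eBayes, with the replicate block and with the slide row as a block; leaving out 1 array gave 3 without WT floating 3 and 0 without each other array (0 to 3). With array weights it was 15289. That estimate did not converge and gave KO floating 1 a weight of 35.6 and WT floating 2 a weight of 0.152, so it rests on few arrays and is not a result on the groups. Weights estimated gene by gene, added after this was seen, gave 6165, with a weight of 5.36 on KO floating 1. Without the 2 arrays that oppose their label it was 46, or 131 on the probes of the 8-array fit. The Cbx3 difference, not past the threshold at -5.33, ranged from -8.02 to -3.96 when 1 array was left out, and passed at -7.57 with array weights, -7.43 with weights gene by gene and -8.02 without the 2 arrays.

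For KO adherent against KO floating, the count of 0 became 7 with quantile normalization and 4 with array weights, and 0 to 1 with 1 array left out (1 without KO adherent 1). For KO adherent against WT floating, 1 became 8 with quantile normalization, 4 without the 2 arrays, 0 with normexp, no filter, probes above background on all arrays, only the 2 groups, trend and robust eBayes, both kinds of array weights, the replicate block and the slide row, and 0 to 3 with 1 array left out (3 without WT floating 3, 0 without each other). Features in both contrasts stayed at 0 except for 4 with array weights; 0 to 0 with 1 array left out.

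Without the 2 arrays, the 46 of KO against WT floating became 198 with normexp, 11 with no filter, 129 with probes above background on all arrays, 455 with trend and robust eBayes, 10882 with array weights (not converged, KO floating 1 at 34.2), 4831 with weights gene by gene, and 0 with the replicate block and with the slide row; 0 to 462 with 1 array left out (0 without WT floating 3, KO floating 1 or KO floating 3, 5 without KO floating 2, 320 without WT floating 1, 462 without KO adherent 1). With the KO cultures joined, 3722 became 179 with no filter, 8879 with array weights, 8061 with weights gene by gene and 1846 at 2-fold or more. It was 1981 with the probes of the fit with the cultures apart. With 1 array other than KO adherent 1 left out it was 635 to 5372 (635 without WT floating 3, 697 without KO floating 1, 903 without WT floating 1). Leaving out KO adherent 1 makes the joined fit the same as the preceding one without that array, which gave 462. All settings of these 2 fits were chosen after seeing the data. With the replicate block the joined fit gave 4128.

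The lists passing for KO against WT floating, 7, became 2 with either array weights, 4 with the slide row, 0 with an estimated correlation and 1 with fry. With 1 array left out it was 2 to 9 (2 without KO floating 2, 3 without WT floating 3, 4 without WT floating 1). Here and for KO adherent against KO floating, the only list that passed fry was the erythroid one (adjusted p = 0.0186), which camera did not call. The 7 lists called by camera had a fry adjusted p of 0.819 to 0.917. For KO adherent against KO floating, 5 became 1 with either array weights, 0 with the slide row, 0 with an estimated correlation, 1 with fry and 3 without the 2 arrays (0 to 7; 0 without KO floating 2, 3 without KO adherent 2). Without the 2 arrays, 6 became 3 with probes above background on all arrays, 0 with an estimated correlation and 0 with fry (5 to 10; 10 without KO floating 1). With the cultures joined, 8 became 3 and 4 with array weights and weights gene by gene and 0 with an estimated correlation. With 1 array other than KO adherent 1 left out it was 3 to 9 (3 without WT floating 3, 5 without KO floating 2). Fry passed 9 lists in the joined fit. Among them were protocadherins (adjusted p = 0.0102), stem and proneural genes (0.0082 each) and astrocyte genes (0.00984). Cell cycle (0.39), matrix and cholesterol genes (0.174 each) did not pass fry. Oligodendrocyte (0.0327), dorsal telencephalon (0.0281), non-neural (0.0143) and neighbour genes of Cbx3 (0.00984) passed fry but not camera. Several of these lists hold genes that passed the filter through KO arrays alone. A 2-fold minimum has no meaning for a list test and was not run. Of single lists, the median of cell cycle genes turned to 0.18 with array weights. In the joined fit the test of this list turned with a median of -0.017 without WT floating 3 (-0.72 to -0.017 with 1 array other than KO adherent 1 left out). Immediate early and stress genes turned at 0.043 with array weights, -0.061 with the slide row and -0.057 without KO floating 2 (-0.057 to 1.25 with 1 array left out), and Hox genes in the joined fit at -0.49 with no filter, where the filter had kept genes measured in KO-labelled arrays alone. The cause was not tested, apart from the array weights and this filter. Over single genes, 3421 values under an alternative kept their side of the threshold, 481 lost it, 58 gained it and 250 uncalled ones changed sign.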

Other observations

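In the fit with the KO cultures joined, other lists held passing members without passing camera. Of 50 non-neural developmental regulators 12 passed the probe filter and 5 of these rose, including Pax9 by at least 5.98-fold and Tbx15 by at least 9.74-fold (camera adjusted p = 0.0863). Pax9, Tbx15, T and Gata3 passed the filter through KO arrays alone, which fixes their direction, so the count of rises is no test. Of 25 genes of the HP1 and H3K9 methylation machinery 3 rose and 1 fell: Adnp by 0.69 (SE 0.15), Dnmt3a by 0.64 (SE 0.16) and Pogz by 0.62 (SE 0.14) up, and Zfp57 at -0.75 (SE 0.17), whose second probe had the opposite sign. Of 29 Polycomb genes 1 rose and 1 fell, with Phc2 at -0.69 (SE 0.15). Markers of other cell types passed in both directions: the ependymal gene Spag6 was at least 2.17-fold higher and the ependymal gene Rsph1 at -2.24 (SE 0.51), above background on 2 of 4 KO arrays. Pdgfra, from -2.89 ± 0.20 (SD, n = 2) to -1.39 ± 0.61 (SD, n = 4), and Cspg4, at 0.58 (SE 0.16), rose; they mark mesenchymal and mural cells and also the oligodendrocyte lineage. The microglial genes Itgam, at 0.67 (SE 0.23), and Csf1r, at -0.27 (SE 0.29), did not pass.

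The tests below were chosen after the result was seen, except the counts of splits of the 6 floating arrays. The Cbx3 signal opposed 2 labels. On the 45 genes other than Cbx3 called without these arrays, the array labelled WT floating 2 lay nearer the KO mean for 44. The array labelled KO adherent 2 lay nearer the WT mean for 33. An exchange of the 2 labels would give this and remains a candidate explanation. Both means come from floating arrays, so these distances compare genotype and not culture. They cannot tell an exchange from separate errors in the genotype of the 2 labels. Wild-type RNA mixed as a minor part into a KO sample is argued against by the Cbx3 level of the array labelled KO adherent 2. It differed by 0.014 (log2) from the mean of WT floating 1 and 3. A mixture of mostly wild-type RNA could reach that level and is not argued against. A rise of Cbx3 in adherent culture is argued against by the level of KO adherent 1, -2.03. Other genes go against a plain exchange: Gm14207, picked among 22647 features for following the labels, measured -2.84 on the array labelled WT floating 2 and -6.50 on the array labelled KO adherent 2, and on the latter array 12 of the 45 genes were not nearer the WT mean. Among these, Cpq had 4.42, against 2.10 and 1.88 on WT floating 1 and 3. Pax9 and Six3 are not among the 45 genes and were picked from those passing in the joined fit. On the array labelled KO adherent 2 Pax9 had -1.64 against -4.77 and -5.49, and Six3 -2.06 against 1.92 and 1.42. The exchange thus stays a hypothesis.

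The count of 1 gene as labelled was reached by 1 of the 10 splits of the 6 floating arrays, the labelled one. The highest other count was 0. By features with an unadjusted p under 0.05 in limma the labelled split did not lead. It gave 391, and the other splits gave 47 to 7393. The 7 lists were reached by 3 of the 10 splits, with 8 lists in the highest other; of the 4 splits that part all same-numbered pairs, the others gave 1, 2 and 3 lists. Of 15 splits of the 6 remaining arrays into 2 and 4, 1 gave 3722 genes, the labelled one, and the highest other gave 0 genes but 10 lists, above the 8 of the labelled split. Of the 10 splits of the 5 remaining floating arrays into 2 and 3, the labelled one gave 46 genes and 6 lists, and the highest others 5 genes and 12 lists. With 10 and 15 splits no share under 0.05 can be had. The list counts of the 2 fits without the doubted arrays were thus exceeded by other groupings of the same arrays, and for the 6 floating arrays the 4 splits that part the pairs, themselves uncertain, are too few to decide.

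Hoxa3, Hoxa7 and Skap2, which neighbour Cbx3 in the GRCm38.p6 assembly, were higher in the joined fit. A rise of the Hox genes of all 4 clusters to measurable levels is argued against: 0 of 28 Hoxb, Hoxc and Hoxd genes on the array were well above background on all 4 KO-labelled arrays. A change of the chromosomal neighbourhood of Cbx3, such as DNA of another strain carried with the targeted allele, may be a cause and stays open. Of the tested genes within 25 positions of Cbx3, leaving out the Hoxa genes and Skap2, 0% (0 of 3) passed, against 16.6% of other named genes (Fisher's exact test, p = 1), too few to decide; in the wider list of neighbours fixed beforehand, 2 of 10 passed. No other explanation was tested for these genes.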
